A study of Gallus gallus with 24 samples.

How the data were processed

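Messenger RNA levels were measured in interdigital region 3, the tissue between digits 3 and 4 of the embryonic chicken hindlimb, in 24 libraries. The libraries fall into 4 groups of 6 by incubation time, which was 7 days plus 4, 6, 8 or 11 hours, as given in the sample titles. Libraries were made by Lasy-Seq, a multiplexed RNA-seq method that starts from barcoded reverse transcription, per the labels' protocols. The submitters' processing notes name fastp 0.21.0, BWA 0.7.17-r1188 and Salmon; the role of each tool, the Salmon version, the genome build and the annotation are not given in the sources used here.

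The deposited table holds 30108 Ensembl gene identifiers in rows and 1 column per library, and each column carries the library name given in that sample's description. Although the table is called a count table, the deposited values are on a natural log scale. Taking exp(value) - 1 gave columns that each summed to 1000000, so the deposited values are ln(CPM + 1), where CPM is counts per 1000000 reads. These CPM were whole multiples of what 1 read is worth in each library: of 406811 values above 0, all but 2 came out whole within 0.01 read, which is 99.9995% of them. The reads behind each value could therefore be recovered, and they totalled 690847 to 8134730 per library. The recovered reads were used for depth, for scaling and for 1 alternative test; the main test was run on log values.

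The design written before the data were examined assumed counts and named the quasi-likelihood test of a count model. Because the unit is a log scale, limma 3.58.1 in R 4.3.3 was used instead of it. A count model was also fitted to the recovered reads while the scaling factors were checked; its values are not among those reported. CPM were divided by TMM factors (trimmed mean of M values, trimming 30% of M and 5% of A) computed from the recovered reads, and log2(CPM + 1) was tested with an intensity trend in the variance. Fold changes are on this scale, with a pseudocount of 1, which understates the change of weakly expressed genes. A gene was tested when at least 6 libraries reached 2.26 CPM (10 reads at the median depth) and its reads summed to at least 15, which kept 13783 genes; 2925 had no read in any library. All 24 libraries entered one fit with a shared estimate of the spread and no covariate. The tests were any difference among the 4 times, 11 h against 4 h, each step of the course, and a slope per hour. P-values were adjusted by Benjamini-Hochberg within each test, with a threshold of 0.05. The share of the variance that followed the time groups was tested by permutation, 100000 resamples or all regroupings where these were few, over the 7190 genes with a mean of at least 10 CPM; this test, the 95% intervals of the differences and the single-gene exact tests were added after the data were seen.

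The identifiers could not be paired with gene names. The reference table at hand lists 25635 genes, 0 of them with an Ensembl identifier, so 0 of the identifiers matched. The 29 gene lists fixed beforehand (20 pathway and 9 cell marker lists), the panel of named genes and the W-linked expression check were therefore not evaluated. The naming rule was also narrowed: where a test called no gene, the genes with the smallest p were to be named, up to 3 per comparison, and this was limited to 2 identifiers with higher and 2 with lower values in all, taken in the order 11 h against 4 h, then the steps.

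The library numbers in the descriptions were parted between 283 and 285. The lower range has 14 libraries that include all those at 4 h and 11 h. The upper range has 10, with 5 of 6 libraries at 6 h and 5 of 6 at 8 h. The step between the ranges is no wider than others within the lower range, so the cut is not given by the labels. This division was treated as a possible batch, as a term in the fit and as subsets. Other alternatives were median-ratio size factors, library size only, no filter, a mean of at least 10 CPM, the replicate number as a block, and only the 2 groups compared. Added after the data were seen were pseudocounts of 0.5 and 5, limma-voom on the recovered reads, array weights, leaving out the 3 libraries under 1000000 reads, and a term for a set of genes with 2 levels across libraries. The replicate numbers did not pair the libraries: of 36 pairs of libraries with the same number in different groups, the deviations from the group means correlated above 0.1 in 9. No 2 libraries of a group were copies, since the chi-square per degree of freedom of their reads was at least 8.73. The labels do not say whether each library came from a separate embryo, so p-values measure the spread between these samples.

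The procedure was tested on simulated counts for the 13783 genes, drawn from the real means, library sizes and spread, with 200 genes changed. For 11 h against 4 h, among changed genes with at least 10 CPM, it recovered 37.5% of 1.5-fold, 64.9% of 2-fold and 96.8% of 4-fold changes, with 3 false calls among 84. For 8 h against 6 h these shares were 20.6%, 66.7% and 96.2%, with 11 false calls among 81. With no gene changed, the test of any difference among the times called 0 genes; the other tests were not run on such data. The simulation treats genes as independent. The recovered shares hold for 200 changed genes. Where fewer genes change, the adjustment asks for a smaller p, so these shares overstate what would be recovered.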

Results

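Interdigital region 3 of the chicken hindlimb, the mesenchyme between neighbouring digits that is removed by cell death as the digits separate, was profiled at 7 days of incubation plus 4, 6, 8 or 11 hours, with 6 libraries per time. The study's title places this time course in work on BMP signalling, reactive oxygen species and interdigital cell death. The question addressed here is which transcripts changed within this window of hours. Genes are given by Ensembl identifier, since the sources used here do not pair the identifiers with names.

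Depth differed between libraries and between groups. The mean depth was 5050733 ± 1817461 reads at 4 h, 3365226 ± 2290660 at 6 h, 3502314 ± 2376767 at 8 h and 5163777 ± 1181593 at 11 h (SD, n = 6 each). Replicate 5 at 6 h (747982 reads), replicate 2 at 8 h (894326 reads) and replicate 5 at 8 h (690847 reads) were the only libraries under 1000000 reads. The library numbers in the labels were parted into 2 ranges, a cut that the labels themselves do not give. The 14 libraries of the lower range averaged 5268384 ± 1412456 reads and the 10 of the upper range 2873492 ± 1985583 (SD; two-sided permutation test, p = 0.0025). All libraries at 4 h and 11 h belong to the lower range, against 1 of 6 at 6 h and 1 of 6 at 8 h, so that time and library number are largely confounded in the steps from 4 h to 6 h and from 8 h to 11 h.

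**Figure D1:**
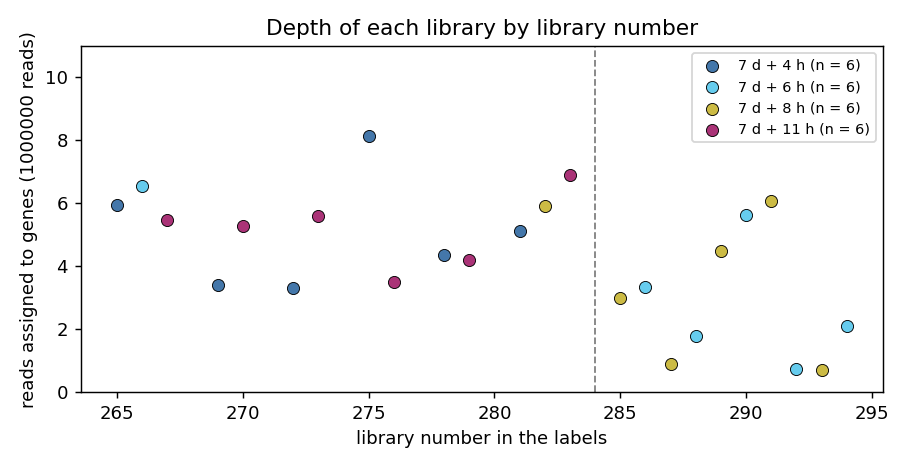
Reads assigned to genes (in units of 1000000 reads, y axis) against the library number in the labels (x axis), 1 point per library, coloured by incubation time; the dashed line parts the lower and the upper range of numbers. The 3 libraries under 1000000 reads all lie in the upper range, and the lower range runs from 3325712 to 8134730 reads.

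Over the whole course no gene differed among the 4 times at an adjusted p under 0.05 (limma, 13783 genes tested). At an unadjusted p under 0.05 there were 1026 genes, against the 689 that evenly spread p-values would give. That number is no bound for chance, since the highest of the splits with shuffled labels gave 1415. With the library number range as a term, which takes up part of any difference between times, there were 581. Limma-voom on the recovered reads called 1 gene, ENSGALG00010021761 (adjusted p = 0.031). This gene also had the smallest p in the main test (adjusted p = 0.10, limma), and its level was 57.9 ± 16.8 CPM at 4 h, 88.9 ± 26.6 at 6 h, 138.2 ± 27.5 at 8 h and 110.9 ± 24.4 at 11 h (SD, n = 6 each). The time groups held 14.2% of the variance over the 7190 genes with a mean of at least 10 CPM, against 13.0% on average with shuffled labels (permutation test, p = 0.171, adjusted p = 0.304 over 6 such tests). Without the 3 libraries under 1000000 reads the share was 16.4% against 14.99% (permutation p = 0.193, adjusted p = 0.304), and 2 genes were called. The 2 ranges of library numbers held 6.50% of the variance against 4.34% with shuffled labels (permutation p = 0.0191, adjusted p = 0.115), and 5.50% against 5.00% without these 3 libraries (permutation p = 0.238, adjusted p = 0.304).

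A steady rise or fall per hour was likewise found for 0 genes at an adjusted p under 0.05 (limma). At an unadjusted p under 0.05 there were 623 genes (limma), below the 689 that evenly spread p-values would give. By limma-voom there were 1061 and with array weights 1113, both above it. Within the lower number range there were 1036, and without the 3 libraries under 1000000 reads 948. Other size factors, other pseudocounts, the replicate block and the range term gave 607 to 651. Limma-voom called 1 gene, ENSGALG00010028554 (adjusted p = 0.048). In the main test it had the smallest p, with a slope of 0.32 ± 0.06 log2 units per hour (SE, adjusted p = 0.10, limma). Its mean level was 23.6 ± 9.55 CPM at 4 h, 51.3 ± 43.2 at 6 h, 67.5 ± 15.5 at 8 h and 110.2 ± 43.3 at 11 h (SD, n = 6 each). Among the 14 libraries of the lower number range alone, 5 genes rose per hour at an adjusted p under 0.05 and 0 fell (limma). Of these libraries 6 were at 4 h, 1 at 6 h, 1 at 8 h and 6 at 11 h. This slope therefore rests almost wholly on 11 h against 4 h and is not a separate result. Without the 3 libraries under 1000000 reads 1 gene rose.

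The widest interval, 11 h against 4 h, lies wholly within one range of library numbers. No gene passed the threshold in the fit of all 24 libraries (limma), and limma-voom called 0. At an unadjusted p under 0.05 there were 524 genes (limma), below the 689 that evenly spread p-values would give. By limma-voom there were 1004 and with array weights 994, both above it. When only the 12 libraries of these times entered the fit there were 983, and without the 3 libraries under 1000000 reads 876. Other size factors, other pseudocounts, the replicate block and the range term gave 512 to 562. ENSGALG00010028554 was 4.42-fold higher at 11 h (log2 difference 2.14 ± 0.45, SE, adjusted p = 0.49, limma), and all 6 libraries at 11 h (53.4 to 155.9 CPM) lay above all 6 at 4 h (17.1 to 41.9 CPM). ENSGALG00010021761 was 1.92-fold higher (log2 difference 0.94 ± 0.21, SE, adjusted p = 0.51, limma), and its 6 libraries at 11 h (84.6 to 151.1 CPM) also lay above those at 4 h (45.1 to 82.6 CPM). For each of these 2 genes the exact permutation test gave p = 0.00216 (two-sided), the smallest that 6 against 6 libraries allow; it does not correct for their having been picked among 13783 genes. Groups did not overlap in 47 of the 7190 genes with at least 10 CPM, or 0.654%, where chance gives 0.216% on average. How far this count varies over other regroupings was not computed, so the difference was not tested. These 2 times held 10.3% of the variance of their 12 libraries against 9.09% over all regroupings (exact permutation test, p = 0.253, adjusted p = 0.304).

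The outcome of this comparison depended on which libraries set the error. When only the 12 libraries at 4 h and 11 h entered the fit, 5 genes rose at an adjusted p under 0.05 and 0 fell (limma), with log2 differences of 0.62 to 2.14. In all 5 the libraries of the 2 groups did not overlap, which follows largely from their small p in these same libraries and is no further support. ENSGALG00010028554 was one of them (2.14 ± 0.25, SE, adjusted p = 0.00029, limma), and ENSGALG00010021761 was just outside (adjusted p = 0.054, limma). Of the 5, 0 passed in the fit of all libraries, where their ranks by p ran from 1 to 101. The median within-group SD on the log2 scale was 0.35 at 4 h and 0.31 at 11 h, against 0.44 at 6 h and 0.46 at 8 h.

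**Figure D2:**
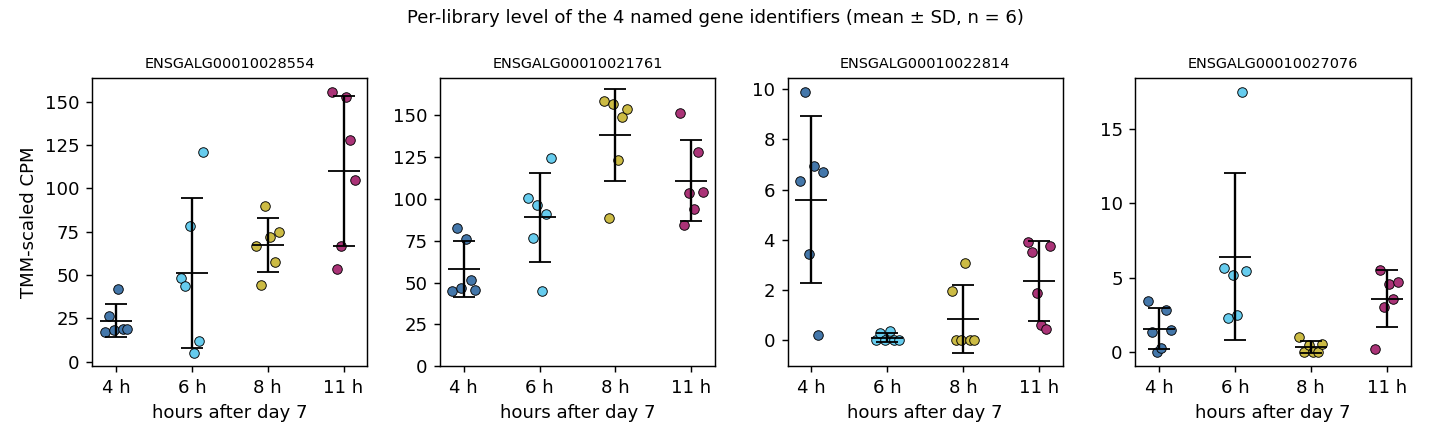
Level of 4 gene identifiers (TMM-scaled CPM, y axis, linear) at 4, 6, 8 and 11 hours after day 7 (x axis); points are libraries and bars are the mean ± SD of 6. The mean of ENSGALG00010028554 is lowest at 4 h (23.6 CPM) and highest at 11 h (110.2), but its libraries at 6 h run from 4.93 to 120.8 CPM. The 2 identifiers on the right stay at or below 17.5 CPM in every library.

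From 4 h to 6 h no gene passed the threshold by limma or limma-voom, and 835 had an unadjusted p under 0.05 (limma). The smallest p was that of ENSGALG00010022814, a weakly expressed gene with 5.60 ± 3.33 CPM at 4 h and 0.111 ± 0.174 at 6 h (SD, n = 6 each), the latter resting on 3 reads in 6 libraries. Its log2 difference was -2.32 ± 0.50 (SE, adjusted p = 0.66, limma) and depended on the scale, with -0.98 at a pseudocount of 5 and -3.97 by limma-voom. Its level was 0.842 ± 1.35 CPM at 8 h and 2.37 ± 1.59 at 11 h (SD, n = 6 each). Without replicate 4 at 6 h and at 8 h, its highest libraries there, the mean was 0.0575 and 0.397 CPM. With the library number range as a term, 0 genes passed and 249 had an unadjusted p under 0.05. That term is set by 6 h and 8 h alone, each with 1 library in the lower range, so the step is then poorly measured. The drop in the count cannot show that library number accounts for the step.

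From 8 h to 11 h there were also 0 genes past the threshold by limma or limma-voom, and 815 with an unadjusted p under 0.05 (limma). With the range term 0 passed, and the share of genes with an unadjusted p under 0.05 was 2.02%, against 5.91% without the term. Since the term rests on 1 lower-range library at 6 h and 1 at 8 h, this drop cannot show that library number accounts for the step. ENSGALG00010028554 differed by 0.62 ± 0.45 (SE) on the log2 scale across this step and ENSGALG00010021761 by -0.31 ± 0.21 (SE).

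From 6 h to 8 h no gene passed by limma or limma-voom, and 1169 had an unadjusted p under 0.05 (limma). In 39 of 100 splits of the libraries the count was as large as 1169. It was 1140 with the range term but 652 by limma-voom. When only the 12 libraries of these 2 times entered the fit it was 635, and within the upper number range 665. The last 3 counts are below the 689 that evenly spread p-values would give. ENSGALG00010027076 had the smallest p, with 6.43 ± 5.64 CPM at 6 h and 0.332 ± 0.407 at 8 h (SD, n = 6 each) and a log2 difference of -2.27 ± 0.49 (SE, adjusted p = 0.37, limma), which was -0.99 at a pseudocount of 5 and -3.31 by limma-voom. The value at 8 h rests on 8 reads in 6 libraries, and the highest library at 6 h, at 17.5 CPM, is replicate 5, one of the libraries under 1000000 reads. Without it the mean at 6 h was 4.21 CPM, and without replicate 1, the highest at 8 h, the mean there was 0.200 CPM; without the 3 libraries under 1000000 reads the log2 difference was -1.77. Among the 10 libraries of the upper number range, 0 genes passed (limma) and the 2 times held 10.5% of the variance against 11.1% under permutation (exact permutation test, p = 0.627, adjusted p = 0.627).

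The size of change these data could leave unseen was bounded from the 95% intervals of the differences on the log2(CPM + 1) scale. On this scale a change is slightly smaller than in CPM at 10 CPM and much smaller at a few CPM. Each interval holds for its own gene, with no correction for the number of genes, so some will miss the true difference. For 11 h against 4 h the interval lay within 2-fold in both directions for 5689 of the 7190 genes with at least 10 CPM (79.1%), and within 1.5-fold for 2489 (34.6%). For 6 h against 4 h, 8 h against 6 h and 11 h against 8 h, 5502, 5292 and 5475 of these genes were bounded within 2-fold. All these intervals come from the fit with one shared error and no library number term. For 6 h against 4 h and 11 h against 8 h they therefore bound time and library number together, not time alone. No such bound is given for the 6593 tested genes below 10 CPM, where this scale compresses changes.

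A set of 28 genes divided the libraries in the same way without following time. These genes were chosen for a gap of at least 1.5 log2 units between neighbouring libraries and for sharing one division, so that an empty range between the levels follows from the choice. The mean log2(CPM + 1) of the set lay between 5.70 and 6.39 in 13 libraries and between 1.35 and 1.94 in the other 11. The high level occurred in 3 of 6 libraries at 4 h, 3 at 6 h, 3 at 8 h and 4 at 11 h, and in 7 of the 14 libraries of the lower number range and 6 of the 10 of the upper one.

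**Figure D3:**
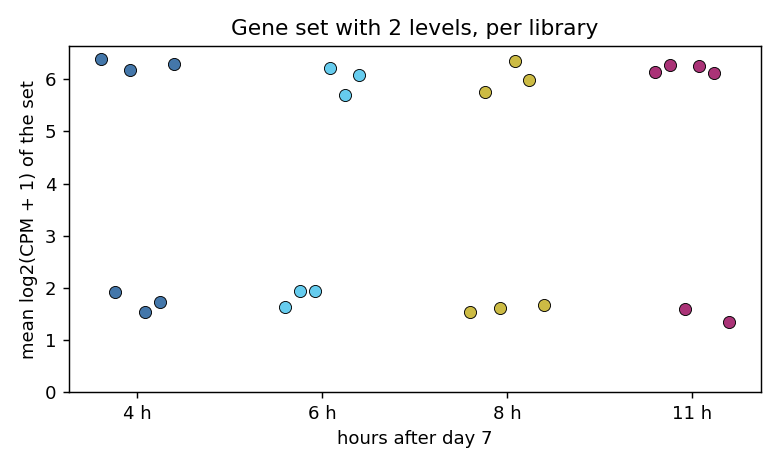
Mean log2(CPM + 1) of the 28 genes with 2 levels (y axis) in each library, grouped by hours after day 7 (x axis); points are libraries. Each time group holds libraries at both levels, 5.70 to 6.39 and 1.35 to 1.94.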

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

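Among 24 sets of 6 libraries examined for a value far from the others (depth, genes detected and the 4 named identifiers at each time), 1 stood out, where chance gives about 1 in 20. ENSGALG00010027076 was at 17.5 CPM in replicate 5 at 6 h, against 2.30 to 5.65 CPM in the other libraries of that time. That library holds 747982 reads, and the value rests on 16 of them.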

How the results depend on the processing

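The 0 calls of the steps 4 h to 6 h, 6 h to 8 h and 8 h to 11 h were obtained under each of their 14, 15 and 14 alternatives. For 11 h against 4 h, 11 of 14 alternatives gave 0 calls; fitting only the 2 groups gave 5 and array weights 3. The settings with limma-voom, array weights, other pseudocounts, left-out libraries or the 28-gene term were chosen after seeing the data; the others were planned. For any difference among the times, limma-voom on the recovered reads gave 1 gene, array weights 3, leaving out the 3 libraries under 1000000 reads 2, and the term for the 28-gene set 1; for the slope per hour these settings and a pseudocount of 5 gave 1 each, and the planned subset of the 14 libraries of the lower number range gave 5. The 28-gene term together with array weights gave 12 genes for 11 h against 4 h, 6 for any time and 25 for the slope (21 higher, 4 lower). ENSGALG00010028554 passed in 3 of its 14 alternatives for 11 h against 4 h (log2 difference 1.97 to 2.21, adjusted p 0.00029 to 0.79, limma) and ENSGALG00010021761 in 2 of 14 (0.89 to 0.98, adjusted p 0.0098 to 0.79, limma); ENSGALG00010022814 (13 alternatives, -3.97 to -0.98, adjusted p 0.43 to 1.00, limma) and ENSGALG00010027076 (14, -3.31 to -0.99, adjusted p 0.27 to 0.98, limma) passed in 0 and kept their sign, with the smallest differences at a pseudocount of 5 and the largest with limma-voom. For 11 h against 4 h the spread by group, the 3 shallow libraries and the 28-gene set are weighed under the other observations; for the other results the cause was not tested. With the replicate number as a block, a number the data do not show to pair the libraries (3 of 24 correlated best with a library of their own number), 0 genes passed in each of the 6 tests. A second count model, planned as a comparison, was not run, and no count-model fit is reported. The tests were kept to the deposited log unit, which was a choice, since the reads could be recovered. The W-linked term, the transcript-level alternative and the gene-list tests were not run because identifiers could not be paired with names and rows are genes. What depth limits was not tested apart from expression level; the bounds on the size of change cover the 7190 genes with at least 10 CPM and leave out the 6593 below.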

Other observations

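Of the tests in this part, the splits of the full fit and those within library number ranges, the effect of the 28-gene term and the spread by group were specified before their results were seen; the others were chosen after. The 28 genes with 2 levels were picked for a wide gap between libraries. The widest separation was 5.68 log2 units between the nearest libraries of the 2 levels, for a gene averaging 720.3 CPM in the 13 high libraries and 6.04 CPM in the 11 low ones. Of the 43 genes with a gap of at least 1.5 log2 units, these 28 shared one division of the libraries and the next most common division was shared by 2.

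A candidate explanation for this set is the sex of the embryos, since birds carry a W chromosome in females only. With the set left out, the first principal component of the 21 libraries with at least 1000000 reads (13.1% of the variance) put 19 of them on the side the set gives. The bound set for this explanation, after the data were seen, was 21 of 21. Missing it does not count against sex, which need not be what this component follows. The chromosome of these genes could not be looked up, so the explanation stays open. The range of library numbers is argued against, since 50% of the libraries in the lower range were high, and so is time, since no group had more than 4 high libraries of 6. Other aspects of library preparation were not tested.

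Each of the 28 genes had reads in the low libraries, from 4 to 406 summed over the 11. Among the 24 of them with at least 50 reads there, the low level was 0.838% to 6.95% of the high level (median 3.41%). Carry-over of reads between libraries as the only source would give every gene the same share, while the highest share was 8.30 times the lowest. A part of it from carry-over, with the rest from reads of related gene copies, may remain and was not tested.

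The absence of calls for 11 h against 4 h was weighed against 3 explanations. The within-group SD at 6 h and 8 h was 1.36 times that at 4 h and 11 h, and 1.04 times without the 3 shallow libraries, so a shared error raised by those libraries may have kept the 5 genes of the 12-library fit from passing. Leaving out the 3 shallow libraries gave 0 calls for this comparison, where at least 10 had been set as the sign of this explanation, but the adjusted p of ENSGALG00010028554 went from 0.49 to 0.082 and that of ENSGALG00010021761 from 0.51 to 0.092 (limma), with log2 differences unchanged at 2.14 and 0.94. The 28-gene term also gave 0 calls against the same 10, and brought both to 0.148, with log2 differences of 2.21 and 0.98; over all alternatives these adjusted p ran from 0.00029 to 0.79 and from 0.0098 to 0.79. A bound of 10 was too high, since the 12-library fit itself calls 5, so the counts of 0 exclude neither explanation and both stay open. The 28-gene term together with array weights gave 12 calls, a setting reached after others had been tried on these data.

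In the fit of all libraries the real count past the adjusted threshold was 0 in each of the 6 tests. Any split reaches a count of 0, so 100 of 100 gave as many and these splits decide nothing; the highest other splits gave 1 gene for any time, 0 for 11 h against 4 h, 19 for 4 h to 6 h, 8 for 6 h to 8 h, 1 for 8 h to 11 h and 2 for the slope. For the 5 genes of the 12-library fit, 5 of 100 splits gave as many, the real one included, so chance could not be excluded. The highest of the other splits gave 73 genes, several times the real count; it put 6 of the 7 libraries with the 28-gene set high on one side, and all 28 genes were among its calls, so this points to that structure of the samples. At an unadjusted p under 0.05, the number of splits with a count as large as the real one was 4 of 100 for any time (1026 genes, highest other 1415). This is under 0.05 for 1 of 6 such tests, uncorrected, and those splits mix the ranges of library numbers. With labels shuffled only within each range, 23 of 100 splits gave as many (highest other 1552). These shuffles keep most of any difference of 4 h and 11 h from 6 h and 8 h, so they do not test it. With the range as a term, which takes up part of such a difference, the count was 581. For what is left once the range is held fixed, chance could not be excluded. The number of splits was 5 for 11 h against 4 h (524, highest other 639), 16 for 4 h to 6 h (835, 1605), 39 for 6 h to 8 h (1169, 1879), 11 for 8 h to 11 h (815, 1028) and 57 for the slope (623, 1818).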
